A study of Homo sapiens with 8 samples.

How the data were processed

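YTHDF2 iCLIP2 was made from HEK293T cells in 2 groups of 4 libraries each, treated for 12 h with 20 µM STM2457 in 0.2% DMSO or with 0.2% DMSO alone, per the labels. Groups came from the treatment given in each label. Nothing in the labels says whether replicates are separate cultures.

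The deposited list is 1 file with no header, holding for each row a chromosome, a position of 1 nt, a strand, a name and a score. The authors' score is a positive number whose scale, and any normalization behind it, is not given in the sources used here; it is used only to rank sites and to give differences in rank within the list. The submitters' processing notes name FastQC 0.11.8, STAR 2.7.3a, UMI-tools 1.0.0 and bedtools 2.27.1 and the build GRCh38.p12, with no role or order. The site caller, the rule for calling sites and the way replicates were combined are not given in the sources used here. The list has 0 columns with values of a single sample, so there is no depth per library, no replicate error and no comparison of STM2457 with DMSO. Filters that the authors may have applied before depositing, such as a minimum of crosslinks or a restriction to certain gene types, would shape every count below.

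Rows at the same chromosome, position and strand were joined, keeping the higher score. Positions are given from 1, as in a genome browser. No genome sequence, exon or coding sequence annotation was used here, so the planned tests of transcript region, coding against 3′ untranslated density, DRACH motifs, stop codons, exon junctions, exon length and codon position were not made. A RefSeq gene table on GRCh38.p14 supplied gene names, types and the extent of each gene. Patches of GRCh38 leave the main chromosomes unchanged, and none of the table's coordinates is given. As a check of the join, 99.7% of positions lay in a protein-coding gene, against 59.2%, 60.5% and 50.5% after shifts of 100, −100 and 1000 kb.

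The table gives no strand. Each gene's strand was taken as that of the majority of positions lying in that protein-coding gene alone, and 99.9% of positions were on the majority strand in 2857 genes with 5 or more. Of the positions, 35729 lay in 1 such gene and 200 more were resolved by strand, giving 35929 assigned positions (95.5%). Left out were 1544 in overlapping genes of the same or unknown strand, 12 on the opposite strand, 16 with tied strands and 112 outside protein-coding genes. Readthrough genes were not used.

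Genes to be named were fixed before the data were examined. They are the 10 with the most sites, the 10 with the highest-scoring site, the 8 with the most sites per kb among genes with 10 or more sites, and up to 4 members with the most sites from each of 29 gene lists. Genomic gene length replaced mature transcript length in this rule, and the parts of it that need coding and untranslated regions were not applied. PRR14L, named for its tie, and the symbols MALAT1 and NEAT1 fall outside it. Some genes that the rule selects are not reported here.

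Each list with 5 or more bound genes was compared with 10000 random lists of bound genes, matched on deciles of genomic length (in place of the mature transcript length fixed beforehand), by median sites per kb of gene and, chosen after seeing the data, by mean log2 sites per gene. P-values are two-sided with Benjamini-Hochberg adjustment over the 24 lists tested, at a threshold of 0.05, and the smallest unadjusted p is 2e-04. Genes, not samples, are the units of these tests, and genes are not independent replicates. The pattern for mitochondrially encoded genes matched 0 symbols of the table.

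Gene ends were compared by counting sites in the first and last 1000 nt of genes spanning at least 10000 nt. Intervals came from 1000 bootstraps over genes and p from 100000 random sign flips of each gene's difference. Scores were compared within genes as the difference in median percentile rank between the kinds of site compared, averaged over genes, with the same intervals and sign flips. These comparisons, and those of the parts of the list in the closing section, were chosen after seeing the data.

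Before use, the steps were tested on simulated data. Of 100 random lists of 20 bound genes from the 7424, 5% had p under the threshold and 0% were called after adjustment. Of 10 lists with sites multiplied by 2, 60% were called, and with sites multiplied by 4, 100% were, so a 2-fold difference in a list of that size can be missed. With the direction of each of 6009 genes drawn at random, the ratio of gene ends was 1.03 (permutation p = 0.52), and with 3′ sites doubled it was 2.06. Scores shuffled within 4322 genes gave a difference of −0.0020 percentile points (permutation p = 0.996), and scores raised by a factor of 1.5 gave 9.31.

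Alternatives fixed before the data were examined were merging sites within 50 nt, keeping the higher-scoring part of the sites split at the median, and keeping genes with 3 or more sites. Others were added afterwards. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.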

Results

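YTHDF2 is a cytoplasmic protein that binds RNA carrying N6-methyladenosine (m6A), the methylated adenosine made in mRNA by the METTL3-METTL14 enzyme, and recruits mRNA decay factors. Its contacts with RNA were mapped by iCLIP2, in which ultraviolet light crosslinks protein to RNA, the protein is precipitated with an antibody, and reverse transcription stops at the crosslinked nucleotide. The cells were HEK293T, an established human embryonic kidney line. Of the 8 libraries, 4 came from cells given 20 µM STM2457, an inhibitor of METTL3, and 4 from cells given the solvent DMSO alone at 0.2%, each for 12 h. The stated purpose was to learn which YTHDF2 binding depends on m6A. The list analysed here holds single-nucleotide binding sites, with 1 score per row and no label or value per library, so STM2457 and DMSO were not compared, replicate spread is unknown, and the read depth behind a site is unknown. The comparisons made were therefore among sites, genes and gene groups.

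The list held 43178 rows at 37613 distinct strand-specific positions, with 5565 positions on 2 rows each. Sites on the plus strand numbered 19359 and those on the minus strand 18254. Neighbouring positions on a strand lay a median of 239 nt apart, and 29.7% of positions had a neighbour within 50 nt. The score, whose scale is not given in the sources used here, had a median of 8.67 with quartiles of 3.75 and 20.8, taking the higher score where a position had 2. Over the 5565 positions on 2 rows, the 2 scores were only weakly related (Spearman rho 0.25). The median score was 5.52 in the shorter and 9.06 in the longer part of the list, described in the closing observations. Ranks by score thus depend on which row is used.

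YTHDF2 sites were found in 7424 protein-coding genes, 37.2% of the 19945 in the gene table. AHNAK, which encodes a very large scaffold protein, had the most, with 95 sites on chromosome 11 between positions 62516670 and 62533902 (GRCh38, minus strand). FAT1, an atypical cadherin, had 62 sites on chromosome 4, and MKI67, the proliferation marker Ki-67, had 54 on chromosome 10. Others among the 10 genes with the most sites were the histone methyltransferase KMT2D with 46, TASOR2 with 45, the transcriptional repressor SPEN with 44, the MAX-binding factor MGA and the homeobox gene ZFHX4 with 42 each, and KMT2C with 41. PRR14L and SON also had 41 sites, and the order among these 3 is alphabetical.

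The densest stretch of up to 10 kb was located in each of these genes, with no test against an even spread. In SPEN it held 32 of 44 sites within 7.88 kb on chromosome 1, from 15928186 to 15936067, out of 67.2 kb between its outermost sites. In FAT1 it held 21 of 62 within 9.89 kb, from 186611676 to 186621561, out of 121 kb, and in AHNAK 59 of 95 within 9.94 kb, out of 17.2 kb. The FAT1 gene's highest-scoring site, at 252, was its 5′-most one at 186709677. Over the 7424 genes with a site the median was 3 sites, with quartiles of 2 and 6. A single site was found in 1638 genes, whereas the 930 genes with 10 or more held 37.5% of the assigned sites. The number of sites was only weakly related to genomic gene length, with a Spearman rho of 0.088 across genes, which are not independent replicates. Among higher-scoring sites, taken as those at or above the median score, 8 of the 10 genes with the most sites were still among the 10 with the most sites.

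**Figure D1:**
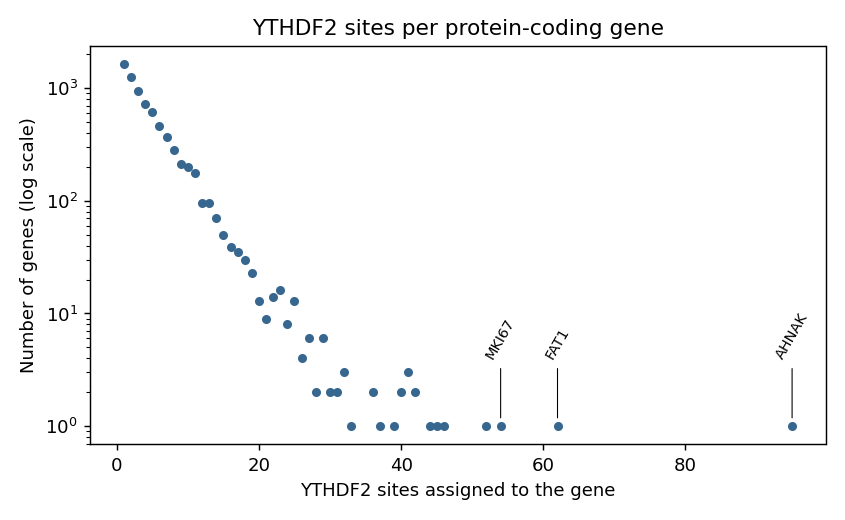
Number of protein-coding genes (vertical axis, log scale) with each number of assigned YTHDF2 sites (horizontal axis), 1 point per observed number of sites. Most of the 7424 genes have few sites, and AHNAK with 95, FAT1 with 62 and MKI67 with 54 lie apart at the right.

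**Figure D2:**
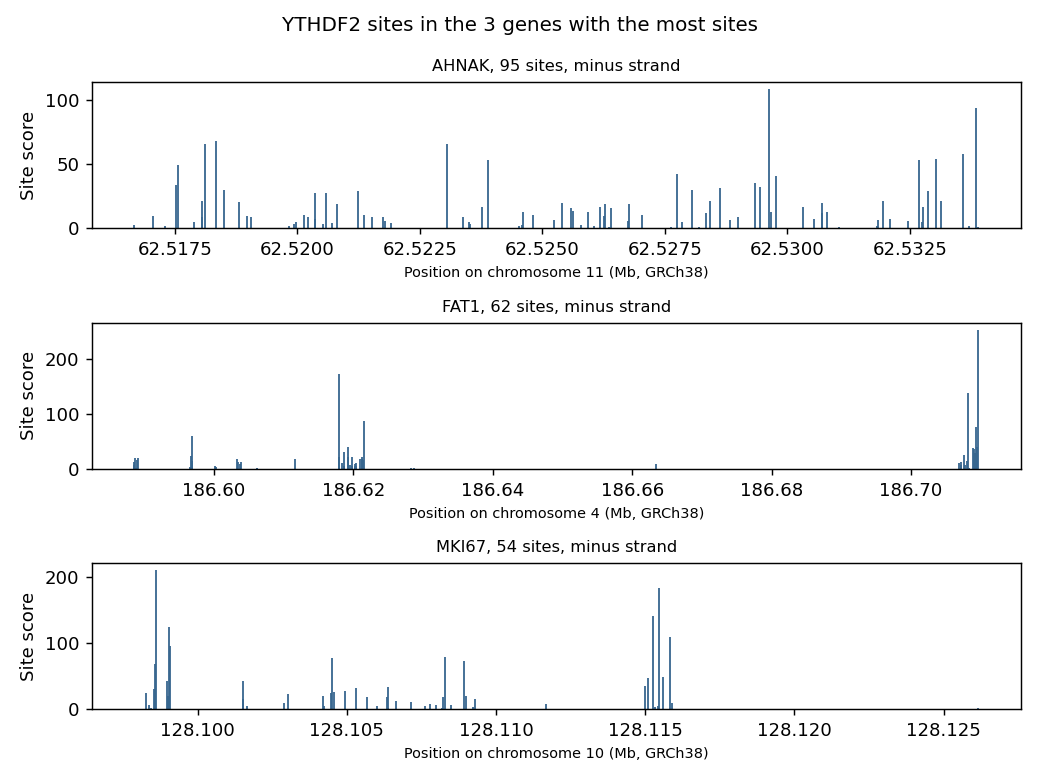
YTHDF2 sites in AHNAK, FAT1 and MKI67, each vertical line being 1 site at its genomic position (horizontal axis, Mb, GRCh38) with its deposited score as height (vertical axis from 0). All 3 genes lie on the minus strand, so transcription runs from right to left; the outermost sites lie 17.2 kb apart in AHNAK and 121 kb apart in FAT1.

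The highest scores lay in other genes than the largest numbers of sites, among them cytoskeletal and chaperone genes. Positions with 2 scores entered with the higher one, though their 2 scores were only weakly related (Spearman rho 0.25). Of the 10 genes with the highest-scoring sites, SRRM2 had 29 sites, SERBP1 10 and the others 8 or fewer. The maximum of 708 was shared by 12 positions, in the cytoskeletal actins ACTB and ACTG1, the chaperones HSPA8 and HSPA1B, the sphingolipid desaturase DEGS1, the mitochondrial phosphate carrier SLC25A3 and the splicing factor SRRM2. ACTB had 2 sites, both at the maximum, at 5527533 and 5527743 on chromosome 7. SERBP1 followed at 680, the dynein light chain DYNLL1 at 665 and the tubulin TUBB4B at 650. No order is given among positions that share the maximum, which may be a ceiling of the score. Actins, tubulins and HSP70 genes have close copies elsewhere in the genome, and how the authors assigned reads among such copies is not given in the sources used here, so scores of these genes are uncertain.

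Among genes with 10 or more sites, sites were densest in short genes. HPS6, a lysosome-related organelle factor, had 17 sites or 6.32 per kb of genomic gene length, all between 102066206 and 102067850 on chromosome 10. FJX1 had 15 sites (6.23 per kb), the tubulin-folding cofactor TBCC 10 (6.23 per kb), UTP3 11 (5.45 per kb) and the selenophosphate synthetase SEPHS2 11 (4.90 per kb). CHST14, ZNF281 and the TFIID subunit TAF7 followed at 4.60, 4.52 and 4.36 per kb. Genomic gene length includes introns, so this ranking favours genes that have few of them.

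Histone lysine methyltransferase and demethylase genes, coactivator and Mediator genes and ZNF zinc finger genes had more YTHDF2 sites per kb than random bound genes of similar genomic length, and genes of the ribosome and respiratory chain fewer. Of 37 histone lysine methyltransferase and demethylase genes, 33 had a site, and the bound ones had a median of 8 sites and 0.131 sites per kb, against 0.0446 in random lists (95% range 0.0283 to 0.0703, adjusted permutation p = 0.0016). NSD1 with 39 sites and ASH1L with 36 followed KMT2D and KMT2C in this group. In NSD1, 20 of 39 sites lay on chromosome 5 from 177209677 to 177211944, and in ASH1L 22 of 36 lay within 4.28 kb on chromosome 1, from 155477974 to 155482253. Coactivator and Mediator genes had 0.0928 sites per kb against 0.0414 (range 0.0219 to 0.0767, adjusted permutation p = 0.029), led by MED13 with 25 sites, the acetyltransferases EP300 with 23 and CREBBP with 20, and MED1 with 18. Of 509 ZNF genes, 302 had a site, with 0.201 per kb against 0.145 (range 0.123 to 0.167, adjusted permutation p = 0.0016), and ZNF318 with 29 and ZNF629 with 25 had the most.

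Cytosolic ribosomal protein genes were often bound, 63 of 88, but 124 sites in all gave a median of 1 per bound gene. Their median density was 0.295 per kb against 0.583 in random lists (range 0.427 to 0.778, adjusted permutation p = 0.0016). RPL28 had the most with 7 sites, then RPL7L1 and RPS24 with 6 each. The list was drawn by gene name, so its 88 members include genes named as like a ribosomal protein, such as RPL7L1. Nuclear-encoded oxidative phosphorylation genes had a site in 51 of 83 cases, at 0.168 per kb against 0.304 (range 0.211 to 0.420, adjusted permutation p = 0.0036). UQCR11 with 7 and NDUFV3 with 6 had the most. By sites per kb this list was not called with the higher-scoring sites alone (log2 −0.74 over random lists, adjusted permutation p = 0.079, against −0.86 with all sites). Replication-dependent histone genes went in opposite directions by measure. They had 2.03 sites per kb against 0.821 (range 0.523 to 1.40, adjusted permutation p = 0.0077), but only 1.16 sites per bound gene as a geometric mean against 2.94 (range 2.15 to 4.08, adjusted permutation p = 0.00096), and 45 of the 69 genes had none. Since only bound genes were compared and 19 of these 24 had a single site, 1 site in each would already give 1.96 per kb, above the random range, so the density call follows from their short length and shows no higher density.

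In all, 4 of 24 tested lists were called higher by sites per kb, 3 of them without the histone genes, and 2 lower, and 5 were higher and 3 lower by sites per bound gene, a measure chosen after seeing the data. By the latter measure m6A writers and erasers had a geometric mean of 8.62 sites against 3.41 (range 1.99 to 5.83, adjusted permutation p = 0.0032), with RBM15B at 23 and RBM15 at 18 sites, and chromatin remodellers 6.68 against 3.60 (range 2.48 to 5.27, adjusted permutation p = 0.0034), with CHD8 at 29 and CHD7 at 28. Neither passed by sites per kb with all sites (adjusted permutation p = 0.082 for each), and chromatin remodellers did with the higher-scoring sites alone (log2 1.06, adjusted permutation p = 0.021). The log2 density of chromatin remodellers was −0.58 without matching on gene length (adjusted permutation p = 0.58). Without matching on gene length, ribosomal protein genes were called in the other direction (log2 1.47, adjusted permutation p = 0.0012). Oxidative phosphorylation genes (0.66, adjusted permutation p = 0.26) and coactivator genes (−0.21, adjusted permutation p = 0.92) also changed sign but were not called. Methyltransferases and demethylases were then no longer called (log2 0.31 over random lists, adjusted permutation p = 0.78). Immediate early genes were called higher there (2.90, adjusted permutation p = 0.0012) and HECT ubiquitin ligases lower (−2.05, adjusted permutation p = 0.0048). With 1 site in each bound gene, density would be 0.183 per kb in the former and 0.0066 in the latter, so gene length alone sets them apart. By sites per gene neither was called (adjusted permutation p = 0.11 and 0.75), so these calls do not show a difference in site number. Among genes with 3 or more sites only the methyltransferase and demethylase list and the ZNF list passed. That setting removes genes with few sites, so it cannot test the lists called lower. The length of the mature mRNA and the expression of each gene were not used here.

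**Figure D3:**
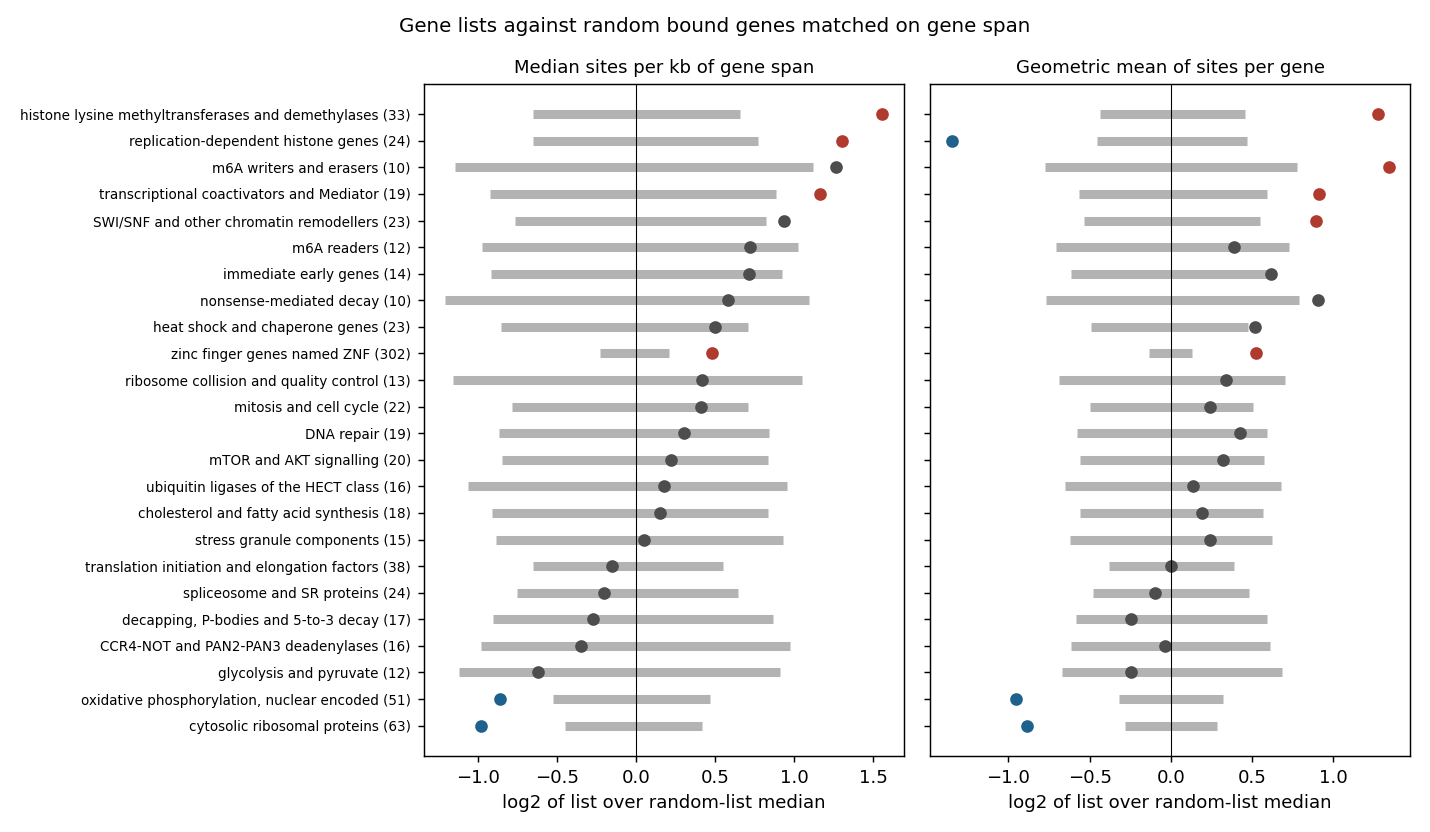
Each of 24 gene lists (rows, with the number of bound members in parentheses) against 10000 random lists of bound genes matched on genomic length, as log2 of the list's value over the random median (horizontal axes), for sites per kb at left and sites per gene at right. Points are the lists, red where higher, blue where lower and dark grey where not called at an adjusted p of 0.05, and grey bars span 95% of the random lists; replication-dependent histone genes are red at left, where their short length sets the value, and blue at right.

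The other lists were not called by either measure. YTHDF2's own gene had 13 sites within 6.11 kb on chromosome 1, from 28737677 to 28743781, and its paralogs YTHDF3 and YTHDF1 had 12 and 11. The m6A readers as a list had 0.118 sites per kb against 0.0714 (adjusted permutation p = 0.38). Among factors of mRNA decay, the deadenylase list had 16 of 18 genes bound (adjusted permutation p = 0.70), with TOB2 at 9 sites and CNOT1, the scaffold of CCR4-NOT, at 7. The decapping list had 17 of 23 bound (adjusted permutation p = 0.71), with the helicase DDX6 at 11, and nonsense-mediated decay 10 of 14 (adjusted permutation p = 0.56), with SMG8 at 20 and UPF1 at 11. Genes of ribosome collision and quality control had sites in 13 of 17 cases (adjusted permutation p = 0.70), led by ASCC3 at 11, and all 15 stress granule genes had a site (adjusted permutation p = 0.93), led by NUFIP2 at 15. Translation factors (adjusted permutation p = 0.75) were led by EIF4G1 at 18, spliceosome and SR genes (adjusted permutation p = 0.74) by SON at 41 and SRRM2 at 29, and chaperones (adjusted permutation p = 0.38) by HSP90AA1 at 12. Immediate early genes had a site in 14 of 29 cases (adjusted permutation p = 0.32), with JUN at 11 and IER5 at 9. Glycolysis (adjusted permutation p = 0.54) was led by TPI1 at 7, cholesterol and fatty acid synthesis (adjusted permutation p = 0.77) by SCD at 10, mitosis and cell cycle (adjusted permutation p = 0.51) by MKI67 and CENPF at 54 and 36, and DNA repair (adjusted permutation p = 0.70) included RIF1 at 18 and MDC1 at 16. HECT ubiquitin ligases (adjusted permutation p = 0.77) included TRIP12 at 14 and HUWE1 at 13, and mTOR and AKT signalling (adjusted permutation p = 0.74), bound in all 20 genes, by IGF1R at 29.

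Sites were more frequent at the 3′ than at the 5′ ends of genes. In 6009 genes spanning 10 kb or more, 3840 of 30158 sites lay in the last 1 kb of the gene and 988 in the first 1 kb, a ratio of 3.89 (bootstrap 95% interval 3.48 to 4.35 over genes). More sites lay at the 3′ end in 1773 genes and at the 5′ end in 473 (permutation test by sign flips, two-sided p = 1e-05, the smallest it can give). Counts from the 3′ end were highest at 300 to 400 nt, with 458 sites, and fell to 91 in the terminal 100 nt. CHD8 had 7 of its 29 sites in the last 1 kb and 0 in the first, and the deadenylase subunit CNOT2 had 6 of 8 and 0, whereas CREBBP and IGF1R had 0 in either. This comparison, like the choice of these examples, was chosen after seeing the data, and it does not separate coding sequence from 3′ untranslated region, since exon boundaries were not used here. For the same reason introns were not removed from either window, so the ratio does not tell whether sites lean to the 3′ end of mature mRNA. By the parts of the list described in the closing observations, the ratio was 1.85 for sites in the shorter part alone and 4.45 for those in the longer part alone.

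**Figure D4:**
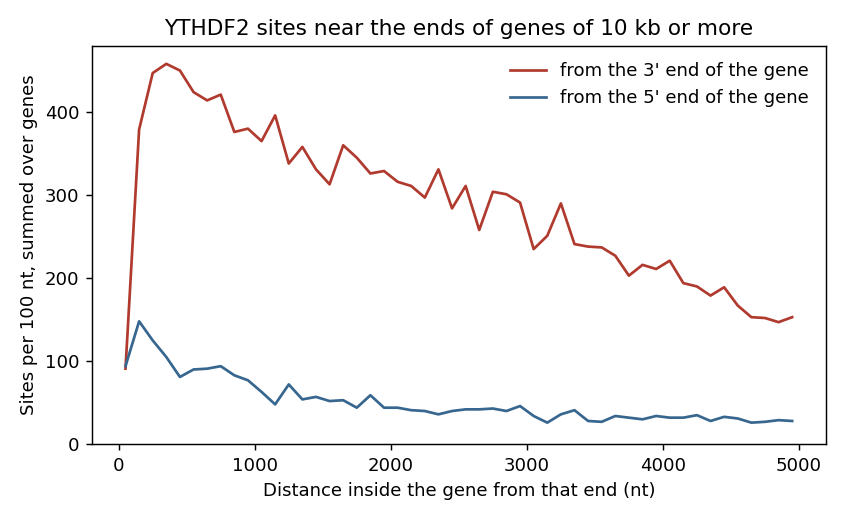
YTHDF2 sites per 100 nt (vertical axis, summed over 6009 genes spanning 10 kb or more) by distance inside the gene from its 3′ end (red) or 5′ end (blue), in nt on the horizontal axis. Counts near the 3′ end peak at 458 in the bin from 300 to 400 nt, and those near the 5′ end peak at 148 from 100 to 200 nt.

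Scores were compared between sites of the same gene. Within 1717 genes with sites of both kinds, sites in the last 1 kb ranked 1.53 percentile points above the other sites (95% interval −0.12 to 3.09, sign-flip permutation p = 0.061), and were higher in 883 genes. This difference was 3.34 points over the last 2 kb (permutation p = 1e-05) and 0.457 in the longer part of the list alone, described in the closing observations (permutation p = 0.59). Sites with a neighbour within 50 nt ranked 3.98 points above those without (95% interval 2.99 to 4.98, permutation p = 1e-05, adjusted p = 1.5e-05 over 3 score comparisons), in 1525 of 2827 genes.

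Nearly all sites lay in protein-coding genes, 37501 positions or 99.7% (exact binomial 95% interval 99.6 to 99.8). The same positions moved by 100 kb fell in such genes in 59.2% of cases, or 60.5% when moved by −100 kb. Of 9 long noncoding RNA genes including MALAT1 and NEAT1, 1 overlapped a single position, which also lay in a protein-coding gene. Small structural RNA genes overlapped 12 positions, all of them inside protein-coding genes as well. No position lay on the mitochondrial chromosome. Whether the authors restricted the list to certain gene types is not given in the sources used here. Such a filter would give these values too, so they do not show a preference of YTHDF2 for protein-coding RNA. Haematopoietic marker genes had a site in 0 of 11 cases, and 4 of 13 neuronal genes did, led by NEFM with 7 and INA with 4.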

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

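The tests on the arrangement of the list were chosen after the arrangement was seen. A signal outside the comparisons of the report was the set of 5565 positions given on 2 rows, 68 of them with equal scores. By the order of its rows the list falls into 4 runs per strand, a new run starting where the chromosomes start again. The first 2 runs of each strand were joined here as a shorter part of 8935 rows. The later runs were joined as a longer part of 34243 rows. No position was repeated within either of these 2 parts. The shorter part shares 62.3% of its positions with the longer one. Which libraries each part stands for is not labelled, and no treatment is assigned to either here. Calls made independently in each part would leave near misses, but 0 sites of the shorter part lay 1 to 3 nt from a site of the longer one, whereas 145 lay 4 to 10 nt away. The smallest spacing was 4 nt within each part and also over all positions together. A rule on spacing applied in each part alone would not keep sites of different parts apart, so the count of 0 argues against calls made independently in each part with no later joint step, and how the positions were set stays open. Whether each part holds the sites of 1 treatment stays open, since the name column holds just 1 distinct name. No biological explanation was tested.

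Another signal outside the main measurement was 112 positions outside protein-coding genes, with 39 in transcribed pseudogenes, 26 in lncRNA genes and 47 in no gene of the table. LINC02693 had 14, CENPBD1P 11 and C19orf48P 8 (all 3 named after their values were seen).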

How the results depend on the processing

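No paired analysis was possible because the list has no values per library, which also rules out leaving out replicates, a replicate block and other splits of the libraries. Alternatives fixed beforehand for the comparison of STM2457 with DMSO and for transcript regions, DRACH motifs, stop codons, exon junctions, exon length and codon position were not run, nor was density over coding and 3′ untranslated length. The use of genomic for mature length, the setting without matching, the longer part of the list alone, positions in a single gene, the sites-per-gene measure, gene ends and scores were chosen after seeing the data. Over the 24 lists, 153 of 167 comparisons with an alternative kept the direction or stayed uncalled on the same side of the threshold, 5 became weaker, 4 stronger and 5 turned. By sites per gene, histone genes turned to −1.35 (log2 over random lists). Without matching on gene length, the log2 value turned to 1.47 for ribosomal protein genes, 0.66 for oxidative phosphorylation, −0.21 for coactivators and Mediator and −2.05 for HECT ligases, methyltransferases and demethylases lost their call (0.31, adjusted permutation p = 0.78) and immediate early genes gained one (2.90, adjusted permutation p = 0.0012); 3 of the 6 called lists were still called there, ribosomal protein genes in the other direction, and the cause was not tested. The adjusted permutation p over all alternatives ranged from 0.00096 to 0.41 for ribosomal protein genes, from 0.00096 to 0.78 for methyltransferases and demethylases, from 0.0012 to 0.52 for immediate early genes, from 0.00096 to 0.93 for oxidative phosphorylation and from 0.00096 to 0.021 for ZNF genes, which were called higher in all 7. The 4 higher lists became 2 among genes with 3 or more sites and 5 with the higher-scoring sites, where chromatin remodellers gained a call (1.06, adjusted permutation p = 0.021, range over its alternatives 0.0034 to 0.58), and the 2 lower lists became 0 there and 1, ribosomal protein genes, with the higher-scoring sites, where oxidative phosphorylation stood at −0.74 (adjusted permutation p = 0.079). Without matching 1 list was lower, HECT ligases, which is neither of those 2. Fewer genes entered the setting of 3 or more sites, which selects genes by the very value compared and removes those with few sites. A single site was found in 34 of 63 bound ribosomal protein genes and 26 of 51 bound oxidative phosphorylation genes. The loss of the 2 lower calls in that setting therefore cannot tell whether they hold. Histone genes had too few members with 3 or more sites to give a value there. The excess at 3′ ends kept its direction and its side of the threshold under the 7 alternatives run, at ratios of 3.30 to 4.76, as did the score difference with a neighbour within 50 nt under 3, at 3.78 to 4.01 points. All 7 alternatives for gene ends used genomic windows that may hold introns. Sites in the shorter part alone, which were not among these alternatives, had a ratio of 1.85. The score difference of sites in the last 1 kb passed the threshold with the mean of the 2 scores (1.78 points) and over the last 2 kb (3.34 points), not with the longer part alone (0.457 points), and the cause was not tested. Genes with a site numbered 7211 with the longer part of the list alone and 5829 with the higher-scoring sites, by construction, and the site counts of the 10 genes with the most sites moved beyond their binomial interval in 10 of 30 cases. Depth per site is unknown and sets no bound here.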

Other observations

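The tests in this part were chosen after seeing the data, and the shares of each list in the 2 parts of the list were seen before any explanation was tested. Ribosomal protein sites were more often in the shorter part of the list than those of other genes. Of their 124 sites, 66 or 53.2% were in it, against 23.8% of all assigned sites and a range of 16.2 to 31.3% in random genes matched on number of sites (adjusted permutation p = 0.0024 over 24 lists). Replication-dependent histone genes (51.7%, adjusted permutation p = 0.0048) and oxidative phosphorylation genes (36.1%, adjusted permutation p = 0.028) were also above their random ranges, and ZNF genes were below theirs at 18.8% (adjusted permutation p = 0.0024). The other 20 lists were not called, the histone methyltransferases and demethylases standing at 22.8%. In the genes with the most sites, TASOR2 had 7 sites in both parts and 0 in the shorter part alone, whereas FAT1 had 14 in both and 7 in the shorter part alone.

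Sites in the shorter part alone leaned less to 3′ gene ends. Their ratio of last to first 1 kb was 1.85 (95% interval 1.52 to 2.28), against 4.45 (3.97 to 5.02) for sites in the longer part alone, a log2 difference of −1.27 (−1.60 to −0.94). Sites in both parts stood at 3.38. Within 2921 genes, sites in both parts ranked 12.9 percentile points higher by longer-part score than sites in that part alone (11.8 to 14.1, sign-flip permutation p = 1e-05, the smallest it can give), and were higher in 68.1% of the genes.

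The excess of ribosomal protein sites in the shorter part was weighed against 2 technical explanations, with bounds written before their results were seen. If strong sites reach both parts, genes with equally high scores should share the excess, and random genes matched on the highest score had 18.8 to 29.1% against 53.2%. Matching used each gene's highest score, but all sites of each gene were counted. Bound ribosomal protein genes had a median of 1 site, against 3 over all bound genes. Weaker sites may therefore lower the share in the matched genes, and this test cannot decide. If sites near the 5′ end were the source, ribosomal protein sites over 1 kb of genomic distance from it should have the usual share. Of the 94 such sites, 54.3% were in the shorter part (bootstrap 95% interval 45.8 to 63.0 over 49 genes). The value of 54.3% argues against closeness to the 5′ end in genomic distance as the whole cause. Genomic distance includes introns, so closeness along the mature mRNA was not tested. What the parts stand for is not labelled, so a biological explanation was not tested.

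The low number of sites in ribosomal protein genes was weighed against pseudogene copies. Reads lost to processed pseudogenes may contribute and stay open. The 32 bound genes with at most 16 named pseudogenes, the median, had a geometric mean of 1.54 sites against 2.273 to 3.97 in matched genes, and the 31 genes with more had 1.71. A first limit of 5 pseudogenes left too few bound genes to test and was replaced by the median before any value was seen, and genes under the median still have many copies. Mature mRNA length, which is short in these genes, was not tested.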
